A study of Rattus norvegicus with 12 samples.

How the data were processed

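RNA was sequenced from primary cultures of rat articular chondrocytes, the cells that make and maintain joint cartilage, taken from the cartilage of the knee. Per the labels, the animals were spontaneously hypertensive rats (SHR) or Wistar Kyoto rats (WKY, the normotensive control strain), at 5 days or 3 months of age. Each of the 4 groups had 3 samples. The labels place replicates 1 and 2 of every group in batch 1 and replicate 3 in batch 2. They give no sex, do not link the collagenase concentrations to samples, and do not say whether the replicates of a group came from separate animals or cultures, so p-values measure the spread between these samples.

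The authors deposited 1 table of expected counts (estimated read counts per gene, which need not be whole), with 16770 genes given by gene identifier and symbol. Bowtie2 2.4.4, RSEM 1.2.28, DESeq2 1.42.1 and the rat assembly Rnor_6.0 are named, per the submitters' processing notes, which do not state the annotation release, the strandedness or any filter. From the values, 9.17% of the deposited expected counts were not whole, and all were rounded to whole numbers before any test. The authors also deposited 5 tables of log2-scale expression, whose transformation is not stated in the labels or the submitters' processing notes. In each of these log2 tables the deposited means of the 2 batches were equal in every gene, to within 7.64e-14, so a batch difference had been taken out before deposit. They were used in 1 alternative only.

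Total counts ran from 17839101 to 20358123 per library. Of the genes in the table, 97 had no counts in any library, and 13397 passed edgeR's filterByExpr by group and were tested. Differences were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood test, TMM scaling), in 1 model over all 12 samples with the 4 groups and the batch as terms. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called where this value was under 0.05. Standard errors of log2 fold changes were derived from the test statistic. Levels are in CPM (counts scaled by library total) with TMM scaling, given as mean ± SD over the 3 libraries of a group, except for Y-linked genes and markers of other cell types, whose CPM is per total count. The SDs hold the difference between batches, which the model takes out.

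5 comparisons were made: the strains at each age, the ages within each strain, and the interaction, which tests whether the strain difference itself differs between ages. The comparisons of the strains at both ages share no library with each other, and neither do the comparisons of the ages. Of the lists of genes written beforehand from known functions and cell types, 31 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the data, and the rotation test fry, were run beside it. Overlaps of called genes were set against the number expected of independent lists and tested with Fisher's exact test. All comparisons use the same model and its estimate of each gene's spread. The lists are thus not independent, and these p-values can be too small.

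The model, the lists, the alternatives described as planned and the rule for naming genes were fixed before the data were examined. In each comparison the rule took called genes with a mean of at least 5 CPM in the higher group, the same direction in both batches and a symbol that is not provisional. It named up to 10 with the largest fold change in each direction, up to 4 members of each summarised list by smallest adjusted p, and a fixed set of 9 genes whatever their values. For an overlap it named the 5 largest in each direction. Where a group had no counts of a gene, a fold is given as a bound from a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% interval. Such floors and intervals cover counting error only. Symbols are those of the table, and 15776 of the identifiers were found in a gene list of a later rat assembly, used for names only.

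Alternatives exchanged the scaling, the test (DESeq2 1.42.0 or limma-voom), the low-count filter, the batch term, the samples in the fit and the list test, and left out each library in turn. Several of these fits leave a group with 2 libraries or 1, and the spread of a gene was then taken from all samples in the fit. The gene and list tests were tested on simulated data made from the means, depths and spread of the real samples, with 200 genes changed. A list of changed genes had a camera p of 9.12e-156, and 0 of 100 random lists had a p under 0.05. Each gene was drawn independently, so this says nothing on lists whose genes vary together. The spread was edgeR's own estimate, and no pair of libraries was made closer than others. The shares of false calls given next may thus favour edgeR. For SHR against WKY at 5 days, edgeR recovered 84% of the genes changed by a log2 of 2 and 95% of those changed by 4, with 3.76% false calls, and DESeq2 gave 23.6% false calls. For SHR against WKY at 3 months, edgeR recovered 79% and 97% with 4.35% false calls, and DESeq2 gave 28.5%. For the ages in WKY, edgeR recovered 82% and 99% with 4.74% false calls, and DESeq2 gave 19.6%. For the ages in SHR, edgeR recovered 81% and 95% with 3.83% false calls, and DESeq2 gave 14.4%. Mitochondrially encoded genes are not analysed here, since the table holds none of those listed, and neither are read alignments or data of kinds other than RNA. Sequence differences between the strains were thus not examined. Strain differences in counts, also of genes without counts in a strain, may therefore hold differences in how reads were assigned.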

Results

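Gene expression was measured by RNA sequencing in 12 libraries from cultures of articular chondrocytes, 3 for each combination of strain (SHR or WKY) and age (5 days or 3 months). Total counts per library ran from 17839101 to 20358123, so depth differed little between groups. Between 14753 and 15194 genes had at least 1 count per library. Transcripts of Col1a1 (gene 29393), a collagen of bone and fibrous tissue that cultured chondrocytes also make, were abundant in every group, from 14660 ± 10990 CPM in WKY at 3 months to 27550 ± 11500 CPM in SHR at 5 days (SD, n = 3). By edgeR it was called in none of the comparisons, while DESeq2 called it between strains at 3 months (log2 1.14, DESeq2 adjusted p 0.0134, against an edgeR adjusted p of 0.215).

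Many cartilage genes differed between the batches. Of 13397 genes tested, 6056 differed between batches by edgeR with Benjamini-Hochberg adjustment, 3062 higher and 2994 lower in batch 2. Col2a1 (gene 25412), which encodes the main collagen of cartilage, was at 49.1 and 10 CPM in the batch 1 libraries of WKY at 5 days and at 5723 CPM in batch 2. It was at 621 and 674 CPM in the batch 1 libraries of SHR at 5 days and at 24551 CPM in batch 2. Its batch difference was a log2 of 8.25 (SE 1.07). By contrast, Col1a1 was at no less than 8458 CPM (per total count) in any library. Whether the cells kept a chondrocyte state in culture was not tested, and the name chondrocyte follows the labels. In the list of cartilage matrix and identity genes, 17 of 21 tested were higher in batch 2, with a median log2 difference of 2.83 (camera adjusted p 6.43e-06, or an adjusted p of 0.659 with the estimated correlation).

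**Figure D1:**
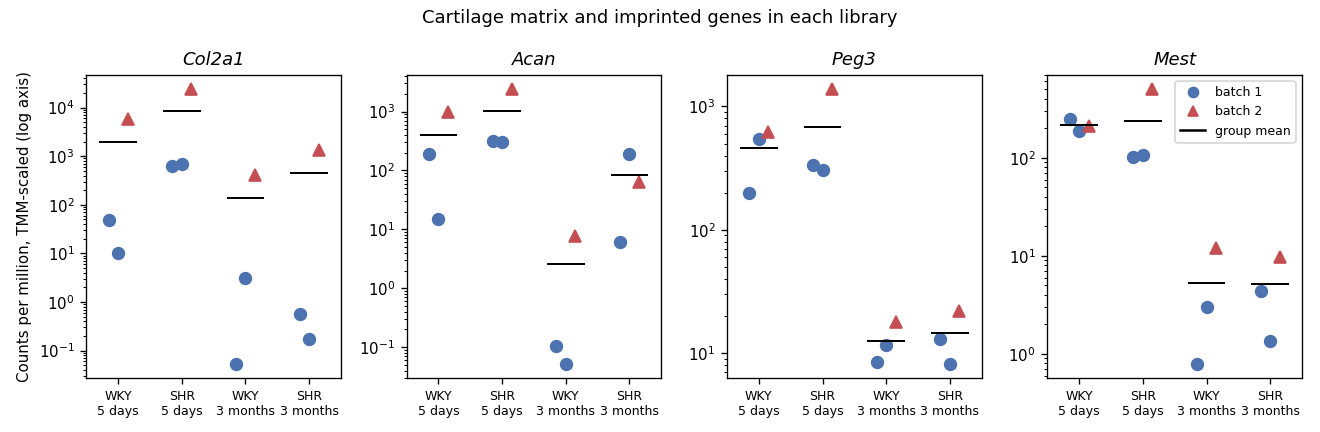
Level of Col2a1, Acan, Peg3 and Mest in each library (TMM-scaled CPM, log axis), with symbols for the batch and a line at the group mean. Col2a1 ran from 10 to 24551 CPM among 5-day libraries and was highest in batch 2 of each group, while every 5-day library had more Peg3 and Mest than every 3-month library.

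How cultures from a hypertensive strain differ from those of its normotensive control soon after birth was asked by comparing SHR with WKY at 5 days. Mettl2b (gene 363687), which encodes a tRNA methyltransferase, was at 24.8 ± 1.64 CPM in SHR and 3.96 ± 1.00 CPM in WKY (SD, n = 3), a log2 fold change of 2.66 (SE 0.20, edgeR adjusted p 0.00112). Atp11b (gene 361929), a subunit of a phospholipid flippase, was at 4.98 ± 0.415 CPM in SHR and 35.4 ± 2.90 CPM in WKY, a log2 fold change of -2.83 (SE 0.23, edgeR adjusted p 0.00135). The class I histocompatibility gene RT1-CE3 (gene 414793) was lower in SHR by a log2 of -3.04 (SE 0.26, edgeR adjusted p 0.00171), at 2.10 ± 0.474 CPM against 17.9 ± 4.94 CPM. The calls of these 3 genes held without any 1 of the 6 libraries and in batch 1 alone. In batch 1 alone, SHR holds only replicates 1 and 2, which lay much closer to each other than other replicates. With both averaged, Mettl2b, Atp11b and RT1-CE3 stayed called (edgeR adjusted p 0.00495, 0.0147 and 0.0147). Septin5 (gene 116728), a cytoskeletal GTP-binding protein, was higher in SHR by a log2 of 2.14 (SE 0.23, edgeR adjusted p 0.0088), at 114 ± 35.9 CPM against 26.9 ± 12.1 CPM. The call of Septin5 was lost without WKY replicate 3 (edgeR adjusted p 0.0511) and without SHR replicate 1 (0.0514).

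Across all genes, 46 of 13397 were called between the strains at 5 days, 20 higher and 26 lower in SHR. Only 6 of them stayed called in each of the 6 fits that left out 1 library: Rpl30, LOC306079, Atp11b, Mettl2b, RT1-CE3 and LOC100362027 (the symbols starting with LOC were named after their values were seen). The count was 14 without WKY replicate 3, 6 without SHR replicate 1, 10 without SHR replicate 2 and 20 without SHR replicate 3. With batch 1 alone it was 22. The balance of directions turned to 16 higher and 6 lower in batch 1 alone, 13 and 7 without SHR replicate 3, 19 and 15 without WKY replicate 2, 8 and 6 without WKY replicate 3, 9 and 4 with only the groups compared, 9 and 7 with the replicate number as a term in place of the batch, and 6 and 5 with no batch term. The count was 8 with SHR replicates 1 and 2 averaged, and 15 without WKY replicates 2 and 3, the only libraries with Y-linked transcripts at 1 CPM or more. SHR replicates 1 and 2 lay much closer to each other than other replicates and are not stated to be separate cultures. Called genes outside those 6 included Vdr, the vitamin D receptor (log2 1.38, SE 0.22, edgeR adjusted p 0.0358), and the homeobox gene Irx3 (log2 -1.93, SE 0.30, edgeR adjusted p 0.0332), each lost in 5 of the 6 fits, which kept them only without WKY replicate 1. Across those fits the edgeR adjusted p reached 0.198 for Vdr and 0.21 for Irx3, in both cases without SHR replicate 2.

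Among gene lists at 5 days, 12 of 31 were called by camera with the preset correlation, 4 higher and 8 lower in SHR, and 0 with the estimated correlation or by fry. Genes of cytokines and of the NF-kB response were lower in SHR, with a median log2 fold change of -1.04 and positive values in 2 of 26 genes (camera adjusted p 1.17e-10, or an adjusted p of 0.307 with the estimated correlation). None of these was called over all genes, and 2 were lower when adjusted over the list alone. The chemokine gene Ccl2 was at 48.2 ± 38.6 CPM in SHR and 538 ± 162 CPM in WKY, and Ccl7 at 10.6 ± 9.12 CPM and 172 ± 136 CPM. The macrophage gene Lyz2 was at 42.9 CPM in WKY replicate 1 and at most 0.845 CPM in the other 5-day libraries. The list of synovial lining and tendon genes was also lower in SHR, with a median of -1.14 and positive values in 3 of 8 (camera adjusted p 0.0017, or an adjusted p of 0.233 with the estimated correlation, fry adjusted p 0.0619). Over all genes 1 was lower (Tnmd, lost without any 1 of the 6 libraries, at edgeR adjusted p from 0.0686 to 0.264), and 3 when adjusted over the list alone. The list call held in all 12 fits that left out 1 library (camera adjusted p of up to 0.0202). Class I histocompatibility genes were lower in SHR by a median log2 of -0.773 (camera adjusted p 4.08e-10, or an adjusted p of 0.307 with the estimated correlation). Of these, 2 were called over all genes, RT1-CE3 and RT1-N2, and 2 higher and 11 lower when adjusted over the list alone. Reads were assigned on the assembly Rnor_6.0, and sequence differences between the strains were not examined. The counts of these genes may therefore not reflect expression alone. The call of RT1-N2 was lost without WKY replicate 3 or any 1 SHR library (edgeR adjusted p from 0.0632 to 0.126). Interferon response genes had a median of -0.795, with 0 called over all genes and 5 lower when adjusted over the list alone (camera adjusted p 5.51e-06, or an adjusted p of 0.307 with the estimated correlation).

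Genes of cholesterol synthesis were higher in SHR at 5 days, with positive log2 fold changes in 23 of 24 and a median of 0.608 (camera adjusted p 1.52e-09, or an adjusted p of 0.439 with the estimated correlation). None was called over all genes or when adjusted over the list alone, and among its members Msmo1 was at 226 ± 28 CPM in SHR and 116 ± 25 CPM in WKY, while Lss went the other way (66.3 ± 4.96 and 105 ± 22.6 CPM). The list was no longer called without WKY replicates 2 and 3 together (camera adjusted p 0.429). Cartilage genes were higher in SHR by a median log2 of 0.524, with 0 called over all genes and 3 when adjusted over the list alone (camera adjusted p 0.00145, or an adjusted p of 0.307 with the estimated correlation). That call was lost without SHR replicate 3 (camera adjusted p 0.208), without both WKY replicates 2 and 3 (0.179) and with no batch term (0.0684). Col2a1 had a log2 fold change of 4.14 (SE 1.32, edgeR adjusted p 0.305) and Acan, the main proteoglycan of cartilage, of 1.51 (SE 1.30, edgeR adjusted p 0.819). Prg4, which encodes the joint lubricant lubricin, was at 0.856 ± 0.471 CPM in SHR and 53.7 ± 38.4 CPM in WKY (edgeR adjusted p 0.0677).

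Whether the strains differ in adulthood was asked by comparing SHR with WKY at 3 months. Mettl2b was again higher in SHR, at 20.5 ± 2.27 CPM against 3.17 ± 0.701 CPM (SD, n = 3), a log2 fold change of 2.70 (SE 0.20, edgeR adjusted p 0.000697). Septin5 was at 136 ± 66.4 CPM in SHR and 25.6 ± 21.2 CPM in WKY, a log2 fold change of 2.58 (SE 0.24, edgeR adjusted p 0.0028). Atp11b was lower in SHR by a log2 of -3.18 (SE 0.23, edgeR adjusted p 0.000697), at 3.47 ± 1.06 CPM against 31.5 ± 6.51 CPM, and RT1-CE3 by a log2 of -2.34 (SE 0.25, edgeR adjusted p 0.00755). These 4 calls held without any 1 of the 6 libraries and in batch 1 alone. Enpp1 (gene 85496), an enzyme that makes the mineralization inhibitor pyrophosphate, was at 259 ± 149 CPM in SHR and 686 ± 331 CPM in WKY, a log2 fold change of -1.46 (SE 0.17, edgeR adjusted p 0.0115). Among the fits that left out 1 library, Enpp1 lost its call only without WKY replicate 1 (edgeR adjusted p 0.0508). At 5 days its log2 fold change was -1.08 (SE 0.17, edgeR adjusted p 0.0358), called in 1 of the 6 fits that left out a library, the one without WKY replicate 2, with an edgeR adjusted p of up to 0.222 in the others.

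In all, 48 genes were called between the strains at 3 months, 18 higher and 30 lower in SHR, of which 8 stayed called in each of the 6 fits that left out 1 library. The count was 11 without WKY replicate 1, 17 without WKY replicate 2 and 29 without SHR replicate 2, and rose to 79 without SHR replicate 3. With batch 1 alone it was 71, and with SHR 5-day replicates 1 and 2 averaged it was 25. The balance of directions was not stable either, with 52 higher and 19 lower in batch 1 alone, 45 and 34 without SHR replicate 3, 37 and 29 without WKY replicate 3, 15 and 14 without SHR replicate 2, and 339 and 268 with DESeq2. S1pr3 (gene 306792), a receptor for the lipid sphingosine 1-phosphate, was at 102 ± 68.2 CPM in SHR and 10.2 ± 2.55 CPM in WKY (log2 3.15, SE 0.50, edgeR adjusted p 0.0336), and was called in the fits without WKY replicate 3 and without SHR replicate 1. Its edgeR adjusted p in the remaining fits ran from 0.0547 without SHR replicate 3 to 0.207 without WKY replicate 1. Loxl2 (gene 290350), which crosslinks collagen, was at 319 ± 117 CPM in SHR and 131 ± 55.0 CPM in WKY (log2 1.30, SE 0.22, edgeR adjusted p 0.044), and lost its call without any 1 of the 6 libraries, with edgeR adjusted p from 0.0573 to 0.192. Rspo3, an enhancer of Wnt signalling, was lower in SHR (2.33 ± 1.38 against 17.8 ± 4.80 CPM, edgeR adjusted p 0.0453) and likewise lost its call in each of these fits, at edgeR adjusted p from 0.0584 to 0.19.

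Among lists at 3 months, 10 of 31 were called by camera with the preset correlation, 5 in each direction, 0 with the estimated correlation and 1 by fry. Genes of the actomyosin cytoskeleton and targets of YAP and SRF were higher in SHR, with positive log2 fold changes in 26 of 26 and a median of 0.919 (camera adjusted p 7.1e-11, or an adjusted p of 0.602 with the estimated correlation). None was called over all genes or when adjusted over the list alone, and Ctgf was at 5749 ± 2331 CPM in SHR and 2235 ± 2142 CPM in WKY. Pericyte and smooth muscle genes were also higher, with a median of 1.62 and positive values in 6 of 8 (camera adjusted p 0.0263, or an adjusted p of 0.602 with the estimated correlation, fry adjusted p 0.171). Over all genes 0 were called, and 5 were higher and 1 lower when adjusted over the list alone. The list call was lost without WKY replicates 1 or 2 or SHR replicates 2 or 3 (camera adjusted p from 0.055 to 0.0705). Cholesterol synthesis genes had a median of 0.757 with 23 of 24 positive (camera adjusted p 1.86e-09, or an adjusted p of 0.602 with the estimated correlation). None was called over all genes, and 14 were higher and 1 lower when adjusted over the list alone, with Msmo1 at 158 ± 82.6 CPM in SHR and 53.4 ± 10 CPM in WKY. Fibroblast-like markers had a median of 0.631, with 1 called over all genes (Loxl2) and 7 higher when adjusted over the list alone (camera adjusted p 3.52e-05, fry adjusted p 0.0444, or a camera adjusted p of 0.223 with the estimated correlation). Class I histocompatibility genes had a median of -0.62 (camera adjusted p 0.00369, or an adjusted p of 0.75 with the estimated correlation), with 1 higher and 2 lower over all genes and 4 in each direction when adjusted over the list alone. That call was lost without SHR replicate 2 (camera adjusted p 0.234). Cartilage genes were not called as a list (median 0.40, camera adjusted p 0.984).

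Some of the largest strain differences lay in genes whose symbols mark a copy of another gene, and their levels are uncertain, since reads of a copy can be assigned to its partner. Rpl30 (gene 64640), a ribosomal protein gene, was at 213 ± 40.0 CPM in SHR and 1.06 ± 0.737 CPM in WKY at 5 days (log2 7.62, SE 0.51, edgeR adjusted p 0.000803). Its copy LOC100362027, named after its values were seen, went the other way by a log2 of -7.54 (SE 0.65, edgeR adjusted p 0.00171). Summed, the pair had a log2 fold change of -0.10 at 5 days and -0.14 at 3 months. Hmgb2, a chromatin protein gene, and its copy Hmgb2l1 moved apart likewise at 5 days, by a log2 of -3.33 and 3.02, and their sum by -0.31. Both Hmgb2 calls were unstable, with Hmgb2l1 lost without any 1 library (edgeR adjusted p from 0.0537 to 0.126) and Hmgb2 lost without WKY replicate 3 or SHR replicates 1 or 2 (from 0.0673 to 0.132). Ndufa10l1, a copy of a mitochondrial complex I gene, had no counts in WKY at 5 days and 741 in SHR, so it was at least 244-fold higher in SHR, and at 3 months the ratio was 255 (95% counting interval 86.9 to 1240). Its call was lost at 5 days without SHR replicates 1 or 2 (edgeR adjusted p 0.0684 and 0.054) and at 3 months without WKY replicates 1 or 2 (0.0593 and 0.05).

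**Figure D2:**
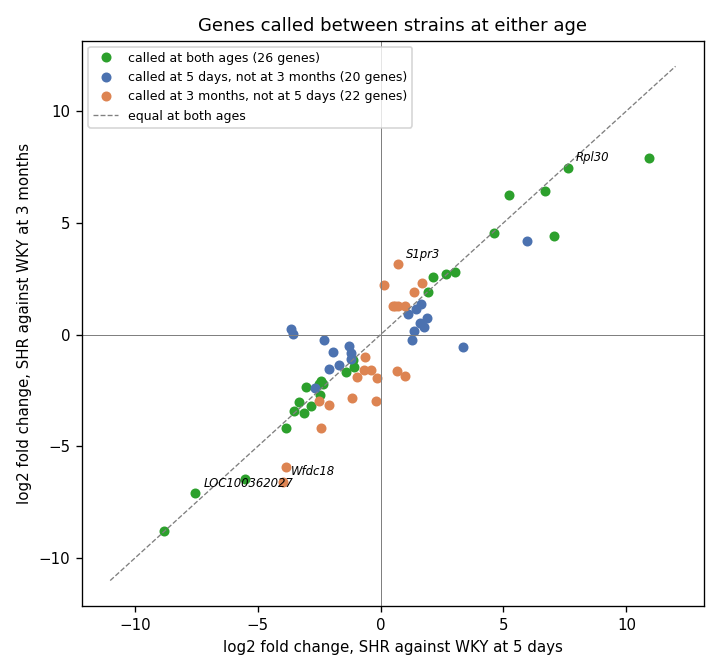
Log2 fold change of SHR against WKY at 5 days (horizontal) and at 3 months (vertical) of the genes called at either age, with colours for genes called at both ages (26), at 5 days only (20) and at 3 months only (22). Rpl30 lies at 7.62 and 7.47, and fitted values of genes with a group at no counts are not bounds.

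Whether strain differences recur with age was asked from the overlap of the calls. Of the genes called at 5 days, 10 of those higher in SHR and 16 of those lower were called in the same direction at 3 months, against 0.0269 and 0.0582 expected of independent lists (Fisher's exact test p 1.57e-25 and 1.50e-38). No gene was called in opposite directions, and 42 of the 46 genes called at 5 days had the same sign at 3 months. Many shared genes have current symbols that mark a copy or relative of another gene. Higher in SHR these were Rpl30, LOC306079, Ndufa10l1, Hmgb2l1, LOC690155, LOC100360940 and LOC102548695, and lower Hmgb2, LOC100362027 and Uap1l2. The RT1 genes RT1-CE3 and RT1-N2 were also shared. A strain difference in how reads were assigned would recur at both ages too, so the overlap cannot tell it from expression. Besides Mettl2b, Septin5 and the copies described above, the shared genes of largest fold included Galr2, a receptor for the neuropeptide galanin (log2 -3.53 at 5 days and -3.40 at 3 months), Cyp39a1, an oxysterol hydroxylase (-3.11 and -3.50), and RT1-N2 (-3.84 and -4.20). The interferon-induced gene Ifi44l had a WKY to SHR ratio of 56.8 at 5 days (95% counting interval 15.4 to 475) and 110 at 3 months (30 to 912). Uap1l2, by its symbol a copy or relative of Uap1, had no counts in SHR and was at least 58.1-fold and 57.8-fold lower there. It made at most 1.85% of the summed counts of genes with related symbols, and that sum was not called at either age. At 5 days Galr2, Cyp39a1, Ifi44l and Uap1l2 were each called in 1 of the 6 fits that left out a library (Cyp39a1 and Ifi44l without WKY replicate 1, Galr2 and Uap1l2 without WKY replicate 2), with edgeR adjusted p of up to 0.176 in the others. In such fits at 3 months Cyp39a1 and RT1-N2 were lost only without WKY replicate 1 (edgeR adjusted p 0.0593 and 0.0537). Among them Galr2 was called only without WKY replicate 2, and Uap1l2 only without SHR replicate 3. Ifi44l was called without these 2 libraries or WKY replicate 3 (up to 0.14 in the other fits). Cyp39a1 was also not called at 3 months in batch 1 alone (edgeR adjusted p 0.0532). Both comparisons used the same estimate of each gene's spread, so the lists were not independent and the expected numbers can be too low. Fitting each age from its own groups left 3 shared genes, and averaging SHR 5-day replicates 1 and 2 left 8.

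What differs in these cultures between early life and adulthood in the control strain was asked by comparing WKY at 3 months with WKY at 5 days. The paternally expressed imprinted gene Peg3 (gene 103691034) fell from 457 ± 226 to 12.7 ± 4.72 CPM (SD, n = 3), a log2 fold change of -5.19 (SE 0.49, edgeR adjusted p 0.00283). Mest (gene 58827), another imprinted gene tied to growth, fell from 215 ± 29.2 to 5.25 ± 5.94 CPM, a log2 fold change of -6.04 (SE 0.74, edgeR adjusted p 0.00556). Igf2bp1, which encodes a fetal mRNA-binding protein, fell by 5.39 on the log2 scale (SE 0.69, edgeR adjusted p 0.00669), and Nrk, a kinase gene, by 6.60 (SE 0.78, edgeR adjusted p 0.00556). Tnmd (gene 64104), of the list of synovial lining and tendon genes, had no counts at 3 months. This was at least 411-fold below its level at 5 days (20.5 ± 14.5 CPM). Cyp4b1, a cytochrome P450 gene, rose from 0.517 ± 0.553 to 13.4 ± 3.97 CPM (log2 4.86, SE 0.62, edgeR adjusted p 0.00669). These calls held without any 1 of the 6 libraries and in batch 1 alone.

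In WKY, 501 genes were called between the ages, 229 higher and 272 lower at 3 months, and 404 of them changed by a log2 of at least 1. Of the 501, 89 stayed called in each of the 6 fits that left out 1 library. The count was 281 without 5-day replicate 1, 228 without 5-day replicate 3, 112 without 3-month replicate 1 and 134 without 3-month replicate 2. With batch 1 alone it was 257, and with SHR 5-day replicates 1 and 2 averaged it was 251. Without 5-day replicates 2 and 3, the libraries with Y-linked transcripts, it was 622 (320 higher and 302 lower), of which 205 were among the 501. More genes were higher than lower also without 3-month replicate 2 (72 and 62), without 5-day replicate 2 (280 and 278) and with limma-voom (272 and 256). The angiotensin receptor gene Agtr2 (gene 24182) fell from 93.5 ± 119 to 0.0740 ± 0.0870 CPM, a log2 fold change of -9.91 (SE 1.34, edgeR adjusted p 0.00758). Of the 6 fits that left out 1 library, only that without 3-month replicate 1 did not call it (edgeR adjusted p 0.0524). The growth factor gene Igf2 (gene 24483) fell from 1415 ± 1437 to 41.6 ± 25.5 CPM (log2 -4.60, SE 0.94, edgeR adjusted p 0.0318). Among the fits that left out 1 library, its call held only in that without 5-day replicate 2, with edgeR adjusted p from 0.0536 to 0.114 in the others. Col3a1, a fibrillar collagen, fell from 3890 ± 1696 to 694 ± 223 CPM (log2 -2.40, SE 0.45, edgeR adjusted p 0.0228), lost without 3-month replicate 1 (0.108) or 2 (0.0873).

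Cartilage genes were lower at 3 months in WKY, with a median log2 fold change of -1.18 (camera adjusted p 0.00523, or an adjusted p of 0.438 with the estimated correlation). Of 21 tested, 1 rose (Sox6) and 2 fell (Col9a3 and Acan) over all genes, and 2 rose and 7 fell when adjusted over the list alone. The list call was lost without 3-month replicate 3 (camera adjusted p 0.163). Col9a3, a collagen of cartilage fibrils, fell from 23.1 ± 38.9 to 0.0754 ± 0.131 CPM (log2 -8.14, SE 0.73, edgeR adjusted p 0.00236), lost without 3-month replicate 3 (0.0619) and in batch 1 alone (0.117). Acan fell from 402 ± 527 to 2.60 ± 4.37 CPM (edgeR adjusted p 0.0458). Among fits that left out 1 library, it was called only without 5-day replicate 2, with edgeR adjusted p from 0.0738 to 0.176 in the others. Sox6, a transcription factor of chondrocytes, rose by a log2 of 1.32 (SE 0.24, edgeR adjusted p 0.0208), lost without replicate 1 or 3 at 5 days (0.0621 and 0.0787) and without replicate 1 or 2 at 3 months (0.0826 and 0.0795). Col2a1 had a log2 fold change of -4.10 (SE 1.35, edgeR adjusted p 0.128), Sox9 of -1.40 (SE 0.47, edgeR adjusted p 0.133) and Prg4 of 0.51 (SE 0.82, edgeR adjusted p 0.749). Cytokine genes were higher at 3 months, with a median of 0.539, 1 gene called over all genes (Il11) and 1 when adjusted over the list alone (camera adjusted p 0.00865, or an adjusted p of 0.586 with the estimated correlation), a call lost without 5-day replicate 2 (camera adjusted p 0.0561). Il11 lost its call without 3-month replicate 1 (edgeR adjusted p 0.0805) or 3 (0.0584). The list of synovial lining and tendon genes was lower at 3 months (median -0.282, camera adjusted p 0.0341, or an adjusted p of 0.438 with the estimated correlation). Of 8 genes 1 fell over all genes and 3 over the list alone, and the list call was lost without any 1 of 4 libraries (camera adjusted p from 0.0569 to 0.0697). Skeletal muscle genes were higher at 3 months, with a median of 0.387 and positive values in 7 of 8 (camera adjusted p 0.0341, or an adjusted p of 0.469 with the estimated correlation, fry adjusted p 0.0623). Over all genes 1 rose (Myod1, log2 3.85, SE 0.64, edgeR adjusted p 0.015), and 2 when adjusted over the list alone. Several members were low, with Actc1 at most at 2.35, Chrna1 at 1.57 and Myod1 at 6.49 CPM in any library, while Acta1 reached 74.4 CPM. Myh1, a muscle myosin gene outside the list, had a log2 fold change of -7.62 (edgeR adjusted p 0.0307). Its call was lost in 5 of the 6 fits that left out a library. The list call was lost without any 5-day library or without 3-month replicate 3 (camera adjusted p from 0.0561 to 0.0866), and that of Myod1 without 5-day replicate 3 or 3-month replicates 1 or 2 (edgeR adjusted p from 0.0537 to 0.06). Of 31 lists, 15 were called by camera with the preset correlation, 1 with the estimated correlation and 5 by fry.

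The same question in the hypertensive strain was asked by comparing SHR at 3 months with SHR at 5 days. Peg3 fell from 677 ± 622 to 14.5 ± 7.08 CPM (SD, n = 3), a log2 fold change of -5.33 (SE 0.49, edgeR adjusted p 0.00274). Rtl3, a gene derived from a retrotransposon, fell from 64.6 ± 92.8 to 0.224 ± 0.244 CPM (log2 -7.60, SE 0.85, edgeR adjusted p 0.00555). Ror2, a receptor for Wnt5a that acts in skeletal growth, fell from 207 ± 84.3 to 68.8 ± 21.5 CPM (log2 -1.55, SE 0.14, edgeR adjusted p 0.00274). Mest fell from 239 ± 233 to 5.13 ± 4.22 CPM (log2 -5.38, SE 0.71, edgeR adjusted p 0.0135), and Scarf1 (gene 303313), a scavenger receptor gene, rose from 1.31 ± 0.935 to 30.0 ± 11.3 CPM (log2 4.60, SE 0.52, edgeR adjusted p 0.00591). These 5 calls held without any 1 of the 6 libraries. In batch 1 alone, where SHR at 5 days holds only the close replicates 1 and 2, Mest (edgeR adjusted p 0.0582) and Scarf1 (0.0706) were not called.

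In SHR, 276 genes were called between the ages, 117 higher and 159 lower at 3 months, and 221 changed by a log2 of at least 1. Only 21 of the 276 stayed called in each of the 6 fits that left out 1 library. The count was 31, 27 and 44 without 5-day replicates 1, 2 and 3, and 40, 492 and 82 without 3-month replicates 1, 2 and 3. The balance of directions turned to 269 higher and 223 lower without 3-month replicate 2, and to 598 and 490 with DESeq2, but was 8 and 36 without 5-day replicate 3. The count was 41 with batch 1 alone and 26 with SHR 5-day replicates 1 and 2 averaged. Eln (gene 25043), which encodes elastin, fell from 3822 ± 1133 to 43.0 ± 43.1 CPM (log2 -6.59, SE 1.18, edgeR adjusted p 0.031). Of the fits that left out 1 library, only that without 3-month replicate 3 called it, with edgeR adjusted p from 0.0505 to 0.113 in the others. Prg4 (gene 289104) rose from 0.856 ± 0.471 to 110 ± 166 CPM (log2 6.04, SE 1.14, edgeR adjusted p 0.0332). Among the same fits it was called only without 3-month replicate 2, with edgeR adjusted p from 0.0788 to 0.148 in the others. Agtr2 had 1459 counts at 5 days and 3 at 3 months, a ratio of 500 (95% counting interval 171 to 2430), and was called without 3-month replicates 2 or 3 (edgeR adjusted p from 0.06 to 0.0896 without any other library). Tnmd had no counts at 3 months, at least 30.9-fold below its level at 5 days. Among the fits that left out 1 library it was likewise called only without 3-month replicates 2 or 3 (edgeR adjusted p from 0.0504 to 0.0747 in the others).

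Cartilage genes were lower at 3 months in SHR, with a median log2 fold change of -1.76 and positive values in 2 of 21 (camera adjusted p 2.35e-09, fry adjusted p 0.00729, or a camera adjusted p of 0.0587 with the estimated correlation). Of these, 4 fell over all genes (Col9a3, Col9a1, Col2a1 and Matn3) and 8 when adjusted over the list alone. Col9a3 fell from 107 ± 181 to 1.64 ± 2.70 CPM (log2 -5.75, SE 0.51, edgeR adjusted p 0.00274), which held without any 1 library but not in batch 1 alone (edgeR adjusted p 0.179). Col2a1 fell from 8615 ± 13800 to 449 ± 777 CPM (log2 -7.84, SE 1.64, edgeR adjusted p 0.0458). Among the fits that left out 1 library, it was called only without 3-month replicate 3, with edgeR adjusted p from 0.0598 to 0.172 in the others. In those fits Col9a1 was lost without 5-day replicates 1 or 2 or 3-month replicate 1 (edgeR adjusted p from 0.0972 to 0.114). Matn3 was called there only without 3-month replicate 2 (edgeR adjusted p from 0.101 to 0.156 in the others). Osteoblast genes were also lower at 3 months, with a median of -1.11 and positive values in 1 of 5 (camera adjusted p 0.0467, fry adjusted p 0.017, or a camera adjusted p of 0.221 with the estimated correlation). None was called over all genes or when adjusted over the list alone, and the list call was lost in 5 of 12 fits that left out 1 library (camera adjusted p from 0.0625 to 0.17). Cytokine and NF-kB response genes were higher at 3 months in SHR, with positive log2 fold changes in 25 of 26 and a median of 2.13 (camera adjusted p 2.91e-12, fry adjusted p 0.0399, or a camera adjusted p of 0.221 with the estimated correlation). Over all genes 1 was called (Ccl7), and 13 when adjusted over the list alone, with Il6 at 4.5 ± 3.5 CPM at 5 days and 77.9 ± 32.4 CPM at 3 months. Among fits that left out 1 library, Ccl7 was called only without 3-month replicate 2, with edgeR adjusted p from 0.0999 to 0.155 in the others. Cholesterol synthesis genes were lower at 3 months in both strains, with medians of -0.677 in WKY (camera adjusted p 4.77e-05, or an adjusted p of 0.583 with the estimated correlation) and -0.501 in SHR (2.29e-05 and 0.525). In WKY 1 was called over all genes and 4 when adjusted over the list alone, and in SHR 0 in either way. Of 31 lists, 17 were called by camera with the preset correlation, 1 with the estimated correlation and 8 by fry.

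The list of genes of juvenile growth and imprinted genes fell in both strains, and was the list called with the estimated correlation in each. Its median log2 fold change was -2.74 in WKY, where 11 of 21 fell over all genes and 15 when adjusted over the list alone (camera adjusted p 1.54e-19, fry adjusted p 0.0011, or a camera adjusted p of 0.0187 with the estimated correlation). In SHR the median was -1.70, with 8 genes over all genes and 14 when adjusted over the list alone (camera adjusted p 1.51e-20, fry adjusted p 0.00151, or a camera adjusted p of 0.0253 with the estimated correlation). With the preset correlation the call held in all 12 fits that left out 1 library, at adjusted p of up to 4.46e-16 in WKY and 8.15e-18 in SHR. In both strains 7 genes fell: Peg3, Mest, Igf2, Plagl1, Igf2bp1, Zim1 and Peg10. All but Igf2 stayed called in WKY without any 1 library, while the other 4 of the 11 each lost their call in some of these fits (edgeR adjusted p from 0.0519 to 0.166). Without 3-month replicates 1 or 2, 6 of the 11 stayed called in WKY, and without any 5-day library or 3-month replicate 1, 3 of the 8 in SHR. In SHR Peg3 and Mest held in each fit that left out 1 library. Among those fits Zim1 was lost without 3-month replicate 1 (edgeR adjusted p 0.0532), and Igf2bp1 without any 1 of the 5-day libraries (from 0.0549 to 0.0688). Plagl1 was lost without any of these or 3-month replicate 1 (from 0.0508 to 0.0584). Peg10 was lost in all those fits but that without 3-month replicate 2 (from 0.0572 to 0.077). Igf2 fell in SHR from 2067 ± 3243 to 23.5 ± 34.6 CPM (log2 -6.13, SE 1.02, edgeR adjusted p 0.0232). Among those fits it was called only without 3-month replicate 2, with edgeR adjusted p from 0.0689 to 0.0789 in the others. The list was not called between strains at 5 days (camera adjusted p 0.487) or 3 months (0.944), nor in the interaction (0.436).

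**Figure D3:**
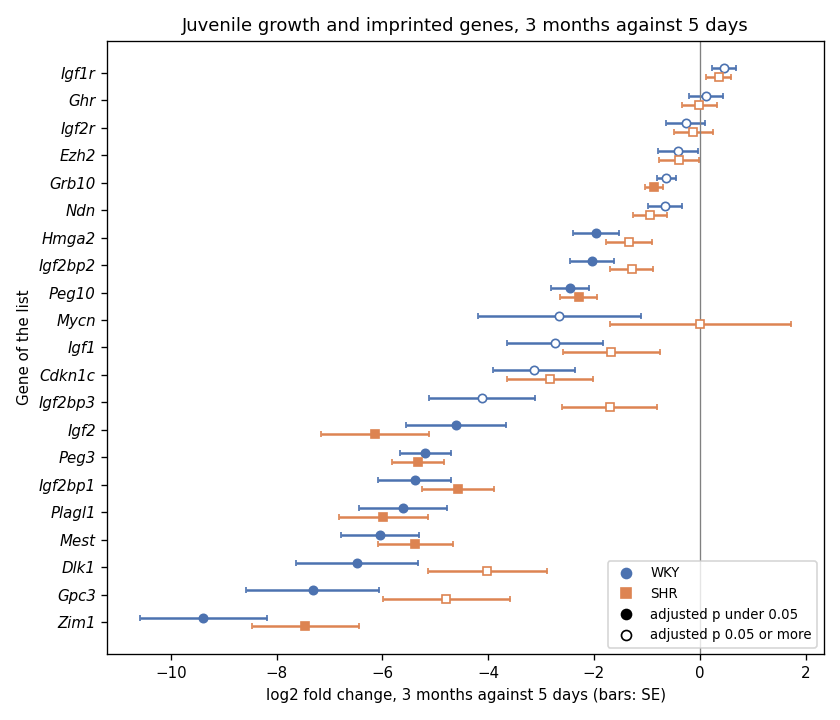
Log2 fold change (± SE) of 3 months against 5 days for the 21 tested genes of the juvenile growth and imprinted list in WKY and SHR, with filled points where the edgeR adjusted p was under 0.05. Of these genes 11 fell in WKY and 8 in SHR, and Peg3 lies at -5.19 and -5.33.

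Whether the ages differ alike in both strains was asked from the overlap of the calls and from the interaction. Of the genes called in either strain, 63 rose and 91 fell in both, against 2 and 3.23 expected of independent lists (Fisher's exact test p 1.92e-82 and 1.77e-116). No gene was called in opposite directions, and 269 of the 276 genes called in SHR had the same sign in WKY. Across genes, which are not independent replicates, the log2 fold changes of both strains correlated with a Pearson's r of 0.637 and a Spearman's rho of 0.633. Shared genes of largest fold included Egln3, an oxygen-sensing hydroxylase gene (log2 4.35 in WKY and 4.66 in SHR), and, falling, Rtl3 (-6.32 and -7.60). The peptide transporter gene Slc15a1 rose by a log2 of 4.78 in WKY, and by a ratio of 38.9 in SHR (95% counting interval 10.4 to 327). Rtl3 stayed called in both strains without any 1 library. Egln3 and Slc15a1 were each called in 3 of 6 such fits in WKY, both lost without 3-month replicate 1, and in SHR only without 3-month replicate 2 (edgeR adjusted p of up to 0.122 and 0.134). The ratio of Zim1 at 5 days to 3 months in WKY was 868 (95% counting interval 155 to 34300) and that of Ppp1r1b, a regulator of a phosphatase, was 534 (95.4 to 21100). Since both comparisons shared an estimate of each gene's spread, the lists were not independent and the expected numbers can be too low. Fitting each strain from its own groups left 29 of the 154 shared genes, and averaging SHR 5-day replicates 1 and 2 left 22.

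In the interaction, 0 genes were called by edgeR, with 569 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0939. limma-voom also called 0, DESeq2 34 and limma on the deposited log2 values 5, and edgeR called 1 with batch 1 alone, 1 without WKY 3-month replicate 1 and 1 without SHR 3-month replicate 2. Prg4 had an interaction log2 of 5.53 (edgeR adjusted p 0.876), Acan of 5.46 (SE 2.08), Col2a1 of -3.74 (SE 1.83) and Igf2 of -1.53 (SE 1.17). Differences between comparisons in which genes were called, such as Eln or Vdr, were thus not shown for any single gene.

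Remaining genes of the fixed set were low or were not called. Cd36, a fatty acid transporter gene with a known defect in some SHR colonies, was at 1.36 ± 1.03 CPM in WKY and 0.675 ± 0.144 CPM in SHR at 5 days (edgeR adjusted p 0.828), and at 0.273 ± 0.293 and 0.885 ± 0.660 CPM at 3 months (0.524). Sox9, the transcription factor that sets chondrocyte identity, was at 35.5 ± 42.4 CPM in WKY and 70.9 ± 94.3 CPM in SHR at 5 days (edgeR adjusted p 0.664). Col10a1, a marker of hypertrophic chondrocytes, reached at most 1.32 CPM and was not tested, and H19 is not among the symbols of the table.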

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

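Of the tests in this part, those of the Y-linked transcripts were chosen after the result was seen, and the tests of gene lists in the interaction were planned. With 0 genes called in the interaction by edgeR (569 at an unadjusted p under 0.05, 0 by limma-voom and 34 by DESeq2), 8 of 31 lists differed between ages in their strain difference by camera with the preset correlation, and 0 with the estimated correlation or by fry. Those whose SHR to WKY difference was higher at 3 months than at 5 days were cytokine and NF-kB response genes (camera adjusted p 7.33e-07, or an adjusted p of 0.595 with the estimated correlation), actomyosin genes and YAP and SRF targets (8.37e-06 and 0.595), fibroblast-like markers (5.94e-05 and 0.208), class I histocompatibility genes (0.0131 and 0.789), leukocyte and macrophage markers (0.0131 and 0.595) and renin-angiotensin and vasoactive genes (0.0286 and 0.595). Those whose difference was lower were cartilage genes (0.0262 and 0.595) and Hedgehog signalling genes (0.0262 and 0.595). In the 12 fits that left out 1 library each, the cytokine, actomyosin and fibroblast-like lists stayed called with the preset correlation in each, and the others were lost in 3 (leukocyte), 5 (cartilage, histocompatibility, Hedgehog) or 6 (renin-angiotensin).

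Y-linked transcripts, which were outside the genes tested, were present in 2 of the 12 libraries, WKY at 5 days replicates 2 and 3. Kdm5d reached 47.98 CPM, Uty 8.219 CPM and Eif2s3y 74.67 CPM there, and at most 0.211, 0.111 and 0.167 CPM in the other 10 libraries, while Ddx3y was at most 0.611 CPM in every library. Since 3 Y-linked genes separated the same libraries, the values are consistent with both libraries holding cells of male animals, and the labels give no sex. As the origin of the strain calls at 5 days these libraries were tested by leaving both out. Of the 46 called genes, 100% then kept their sign and at least 50% of their log2 fold change. At least 80% had been set as counting against this origin. But these genes were called with WKY replicate 1 in the fit. A gene that differed only in the other WKY libraries at 5 days would hardly have been called. With 1 WKY library left at 5 days, the result thus cannot decide the question. Both libraries also lie in the 5-day group of the age comparison in WKY, whose 3-month libraries were all among the other 10. Y-linked transcripts thus differed between the ages in WKY too, and a difference in sex stays open for single genes.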

How the results depend on the processing

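The tests that left out the WKY 5-day libraries with Y-linked transcripts, averaged SHR 5-day replicates 1 and 2, used the deposited log2 values or summed families of related symbols were chosen after the data were seen. In the order SHR against WKY at 5 days, at 3 months, age in WKY, age in SHR and interaction, the counts were 46, 48, 501, 276 and 0. DESeq2 gave 381, 607, 1495, 1088 and 34. Its share of false calls on simulated data was several times that of edgeR, but those data were drawn with edgeR's estimate of the spread. No batch term gave 11, 10, 128, 18 and 0. Fitting only the groups compared gave 13, 23, 268 and 83, and batch 1 alone 22, 71, 257, 41 and 1, both with fewer samples. Averaging SHR 5-day replicates 1 and 2 gave 8, 25, 251, 26 and 0, and limma on the deposited log2 values 81, 27, 374, 150 and 5. Each of these limma counts but that of the interaction came from only the 6 libraries compared. limma-voom gave 73 at 3 months, and was within 1.5 times elsewhere. Leaving out both WKY libraries with Y-linked transcripts gave 15 at 5 days and 622 for age in WKY, of which 205 were among the 501. Summing families of related symbols, which also hold distinct genes, gave 29 and 31 between strains. At 5 days the calls were 20 higher and 26 lower in SHR, but 16 and 6 in batch 1 alone, 13 and 7 without SHR replicate 3, 19 and 15 without WKY replicate 2, 8 and 6 without WKY replicate 3, 9 and 4 with only the groups compared, 9 and 7 with the replicate block and 6 and 5 with no batch term. At 3 months they were 18 higher and 30 lower, but 52 and 19 in batch 1 alone, 45 and 34 without SHR replicate 3, 37 and 29 without WKY replicate 3, 15 and 14 without SHR replicate 2 and 339 and 268 with DESeq2. For age in WKY they were 229 higher and 272 lower, but 280 and 278 without 5-day replicate 2, 72 and 62 without 3-month replicate 2, 320 and 302 without the libraries with Y-linked transcripts and 272 and 256 with limma-voom. For age in SHR they were 117 and 159, but 269 and 223 without 3-month replicate 2 and 598 and 490 with DESeq2. DESeq2 size factors and the other low-count filters kept each count within 1.5 times. Except where fewer samples explain a lower count, the cause was not tested.

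With the replicate number as a replicate block in place of batch, the counts were 16, 28, 336, 157 and 0. Deviations of same-numbered samples from their group means correlated at no less than 0.108, 0.0973 and 0.456 for replicates 1, 2 and 3, while replicate 1 and replicate 2 of other groups correlated at 0.146 to 0.558, so the numbers did not pair samples beyond the batch.

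Without 1 library at a time, counts ran from 6 to 34 at 5 days, 11 to 79 at 3 months, 112 to 558 for age in WKY, 27 to 492 for age in SHR and 0 to 1 for the interaction. The lowest came without SHR 5-day replicate 1 (6), WKY 3-month replicate 1 (11 and 112) and SHR 5-day replicate 2 (27), and the highest without SHR 3-month replicates 3 (79) and 2 (492). Lists called by camera (12, 10, 15, 17 and 8) ran from 8 to 14, 5 to 11, 7 to 17, 12 to 18 and 5 to 11. With the estimated correlation 0, 0, 1, 1 and 0 lists were called, and with fry 0, 1, 5, 8 and 0. Genes shared by the strain comparisons (26) were 3 when only the groups compared were fitted and 8 with SHR replicates averaged, and those shared by the age comparisons (154) were 29 and 22.

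No named gene that was called changed direction. Uncalled values that did were Igf2 at 5 days with no batch term (log2 0.547), Col2a1 at 3 months with only the groups compared (-0.162), in batch 1 (-2.07), without WKY replicate 1 (-0.0223) and without SHR replicate 3 (-2.50, against up to 1.26 without WKY replicate 2), and Sox9 at 3 months without SHR replicate 2 (-0.199, against up to 0.92 without WKY replicate 2). For age in SHR they were Col1a1 with no batch term (-0.0182) and without 3-month replicate 2 (-0.225, against up to 0.44 without 3-month replicate 3), and Cd36 in batch 1 (-0.193) and without 3-month replicate 3 (-0.825, against up to 0.92 without 3-month replicate 2). In the interaction they were Sox9 in batch 1 (0.0385) and without WKY 3-month replicate 2 (0.162, against down to -0.94 without SHR 3-month replicate 2), and Igf2 with limma on the deposited values (0.118). Of the 134 calls of named genes, DESeq2 kept 134, limma-voom 106, the replicate block 84, limma on the deposited values 75, only the groups compared 59, averaging 58, batch 1 alone 53 and no batch term 37. At these depths a group without counts bounds a fold only by its counting floor.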

Other observations

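Of the tests in this part, the splits of the samples were planned in advance, the tests of copies and of cartilage content were chosen after the patterns were seen, and how both were read was changed after a first result. The macrophage genes Lyz2, Adgre1 and Csf1r were highest in WKY at 5 days replicate 1 (42.9, 10.6 and 3.53 CPM). Others of that list peaked elsewhere, Cd68 and Cd14 in SHR at 3 months replicate 3 (12.6 and 51.5 CPM) and Laptm5 in SHR at 5 days replicate 1 (5.55 CPM). Genes of synovial lining and tendon reached 264 (Prg4), 260 (Cd55), 537 (Pdpn) and 156 CPM (Thbs4), those of pericytes 313 (Cspg4) and 112 CPM (Mcam), and Alpl of osteoblasts 96.7 CPM. Whether these came from other cells or from chondrocytes was not tested. The endothelial genes Pecam1 and Cdh5 reached at most 0.224 and 0.211 CPM, the fat cell genes Adipoq and Plin1 0.056 and 0.836 CPM, and the bone genes Bglap and Ibsp 0.279 and 0.540 CPM. Other members of these lists were higher, with Egfl7 at 6.39 to 21.8 CPM and Flt1 at up to 19.9 CPM among endothelial genes, and Lpl at up to 60 and Cebpa at up to 25.9 CPM among fat cell genes. SHR 5-day replicates 1 and 2 differed by a mean chi-square of 4.21 and a median of 0.990 per gene, where counting error alone gives a mean of 1 and a median of 0.455, against means of 38.8 to 327 and medians of 3.68 to 31.9 in other pairs of replicates. The labels do not say whether these 2 libraries are separate cultures, so the 3 SHR libraries at 5 days may hold fewer independent samples, and with both averaged 8 genes were called between strains at 5 days in place of 46.

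Some genes called between strains had symbols that mark a copy or a relative of another gene. Families were formed from related symbols alone, so they also hold distinct genes, such as Loxl2 with Lox, and do not count copies that can share reads. With counts summed over each of 14 families, 2 stayed called, as reads shared between copies would give, but relatives and abundant partners also dilute such sums. In 5 families a called member made at least 50% of the summed counts of a group, and 2 of these stayed called. Dilution does not apply to the Rpl30 pair, where both members were called in opposite directions and 1 made up to 99.56% of the sum. For the families as a set, shared reads were left open. Such families held 23.5% of the 68 called genes against 4.55% of those tested (Fisher's exact test p 4.54e-08), and with RT1 genes and provisional symbols 36.76% against 11.7%. Although this is more than their share, it lay under the 50% set before that test. Copies without a related symbol were not searched, and most of these calls were lost in some fit that left out a library. Of 6 calls at 5 days kept in every such fit, Rpl30, LOC100362027 and LOC306079 lay in these families. By its current symbol LOC306079 is a copy of Rpl14. RT1-CE3 is an RT1 gene, while Atp11b and Mettl2b were in neither group. The share thus cannot decide whether such genes account for the strain calls as a whole.

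The fall of juvenile growth and imprinted genes between 5 days and 3 months could come from fewer cartilage-like cells in the 3-month cultures. With the mean level of cartilage genes as a covariate, the median log2 fold change of the list in WKY was -2.97 with the batch term (bootstrap upper bound -0.881) and -2.73 without it (-1.39), against -2.74 and -2.78 in the same fits without the covariate. In SHR it was -1.195 (-0.886) with the batch term and -2.16 (-0.626) without it, against -1.70 and -2.13, so it shrank clearly only in SHR with the batch term. The bounds come from resampling the genes of the list, not the libraries, so they measure the spread over these genes alone. Above -0.5 was set for this explanation and below -1 against it. Since not every bound lay below -1, these fits left cartilage content open. The criterion as first written, without those bounds, would have counted against this explanation. With the batch term 0 of all 13397 genes were called, so the lost calls say nothing on the list. Without that term, 12 genes of the list fell in WKY and 6 in SHR with the covariate, against 5 and 2 without the covariate. The cartilage score was higher in batch 2 in every group, so there it can also stand in for the batch. The 3-month batch 2 libraries had cartilage scores (mean log2 CPM) of 3.58 and 4.73 and juvenile scores of 2.86 and 2.67. The 5-day libraries of batch 1 had 3.19 to 4.08 and 4.92 to 6.04. Juvenile scores thus differed at like cartilage scores, though these libraries also differed in batch. Between batches the median log2 difference was 2.83 for cartilage genes and 0.298 for the juvenile list (camera adjusted p 0.407). Of the 21 juvenile genes, 6 were called higher and 0 lower in batch 2. These values argue against cartilage content, as scored here, as the only source of the fall, and age itself stays open.

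Each comparison of 3 against 3 samples has 10 splits, too few for a share under 0.05. At 5 days 2 splits gave as many calls as the real one (46), the other calling 1396. That split set WKY replicate 1, the library with most Lyz2, and both batch 2 libraries against the rest, which points to a structure of the samples whose cause was not tested. The 3 other splits with both batch 2 libraries on 1 side gave 0 calls, but the model held the batch as a term in every split, so this says little on the batch as a source. Batch 1 alone gave 22 for the real split. In the other comparisons of strain at 3 months and of age in WKY and SHR, 1, 1 and 1 splits gave as many calls (real 48, 501 and 276, highest other 0 in each). For the interaction the real count was 0 by edgeR (569 at an unadjusted p under 0.05, 0 by limma-voom and 34 by DESeq2), so 100 of 100 splits gave at least as many whatever the data, and this decides nothing. The highest other count, 1002, points to a structure of the samples.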
